A study of Mus musculus with 8 samples.

How the data were processed

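Cerebellar total RNA of 4 alcohol-naive male mice, 2 ILS and 2 ISS, was labelled with biotin and hybridised to Affymetrix 430A and 430B arrays, per the labels. The value tables hold linear signal intensities deposited by the authors, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. From the values, every deposited array had a 2% trimmed mean intensity of 500, so the authors had scaled the arrays before deposit. The tables hold no detection calls, and probe-level intensities were not analysed here. The experiment files recorded with each array are of unit other; per the file headers they name the chip type, fluidics station and scan order deposited by the authors. The titles of some samples leave out which array was used, and the chip type in these files was used to check it. All 4 arrays of a chip were scanned on 1 day. On 430A both ILS arrays were scanned before both ISS arrays, and on 430B both ISS arrays before both ILS arrays. Scan order therefore cannot be told apart from strain on either chip. On 430A both ILS arrays ran on station 2 and both ISS arrays on station 1, and on 430B ILS replicate 48 ran on station 1 and the other arrays on station 2. The replicates are separate mice, so the p-values measure the spread between mice, with 2 residual degrees of freedom per probe set.

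Each array was rescaled to a 2% trimmed mean of 500, log2 transformed, and stripped of the 64 control probe sets. Probe sets whose mean log2 value reached the median of the chip were tested, 11313 on 430A and 11256 on 430B. ILS was compared with ISS within each chip by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment within the chip and a threshold of 0.05. Prior degrees of freedom were 6.22 on 430A and 7.31 on 430B. All tests were two-sided. With no detection calls, a strain was taken as dim at a probe set where both its values lay below the median of their arrays. The fold is then a lower bound, from the mean log2 of the brighter strain minus the mean over the dim strain of the higher of the array median and its own value.

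Genes were taken from the platform annotation, in which 20380 probe sets of 430A had 1 gene symbol, 691 several and 1555 none. On 430B 14661 had 1 symbol, 245 several and 7605 none. Of the gene identifiers, 12369 of 12393 on 430A and 9468 of 9608 on 430B were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. The sources name no genome build for the arrays, so no coordinates are given. No gene was named from a probe set with several symbols.

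Gene lists were fixed before the data were examined, 33 in all, of ethanol-relevant receptors, channels, enzymes and signalling, of stress and metabolism, and of cell types that a cerebellar dissection can hold. They were tested with limma's camera (preset inter-gene correlation of 0.01), with the brightest probe set of each gene and at least 5 measured genes, adjusted over the 31 lists of 430A and the 23 of 430B. A gene counts as measured where a probe set with its symbol alone was among those tested. The named genes were also set before the data were examined: among probe sets with 1 symbol, past the threshold and without overlap between strains, the 10 largest changes per direction on 430A and the 4 largest on 430B, 1 probe set per gene, and in each list up to 4 called members or else up to 2 with the smallest p. Agreement between probe sets of one gene was tested by an exact binomial test with an exact 95% interval, and correlations between the arrays by 100000 permutations.

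The alternatives tried were no rescaling, equal medians, quantile normalization, a floor or a pseudocount at the 20th percentile (45.1 on 430A and 59.4 on 430B), no filter or one at the 75th percentile, eBayes without the trend or robust, joint adjustment of both chips, a 2-fold minimum, leaving out each mouse, the station as a block on 430B, camera with an estimated correlation, fry, and other choices of probe set per gene. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so it had little power with these arrays. Fry was read in its directional form, without its mixed form. Cyclic loess normalization was added after the data were examined. Where a mouse was left out, the lone array of its strain was assumed to vary like the others. The station block on 430B fits ILS replicate 48 exactly, so it rests on the same assumption.

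The steps were tested on simulated data with the means of each chip and 200 changed probe sets, in 10 simulations. Variances were drawn from limma's fitted prior, and the noise was independent between probe sets and arrays. Such data obey the model that limma fits. The shares below hold for that model and do not measure the error rate of the real arrays. On 430A, with 11313 probe sets, 5.37% of changes of 0.5 on the log2 scale, 72.7% of changes of 1 and 99.4% of changes of 2 were recovered, with 5% false calls. On 430B, with 11256, the shares were 1.19%, 30.3% and 92.7%, with 5.94% false calls.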

Results

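RNA from the cerebellum of 4 alcohol-naive male mice was measured, 2 of the Inbred Long Sleep strain (ILS, mice 48 and 51) and 2 of the Inbred Short Sleep strain (ISS, mice 55 and 56). The strains descend from mice selected for long or short loss of the righting reflex after ethanol, and the series compares their baseline expression. Each mouse was measured on the Affymetrix 430A array and on the 430B array, so that 8 arrays gave 2 value tables of 4 arrays. The 430A arrays held 22626 probe sets apart from controls and the 430B arrays 22511. A positive log2 fold change below means a higher signal in ILS, and each value is the mean of 2 mice. The number of mice limits the precision. Arrays of one strain correlated across probe sets at r = 0.975 (ILS) and 0.980 (ISS) on 430A, against 0.938 to 0.962 between strains. On 430B the within-strain values were 0.944 and 0.959 and those between strains 0.926 to 0.942. By median absolute log2 difference the 430B arrays of ILS (0.246) were no closer than those of different strains (0.226 to 0.278), while those of ISS were closer (0.199). The control probe set for the 3' part of 18S ribosomal RNA was 4.63-fold higher in ILS on 430A, at 669 ± 186 against 144 ± 3.68 (SD, n = 2), and 3.8-fold higher on 430B.

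**Figure D1:**
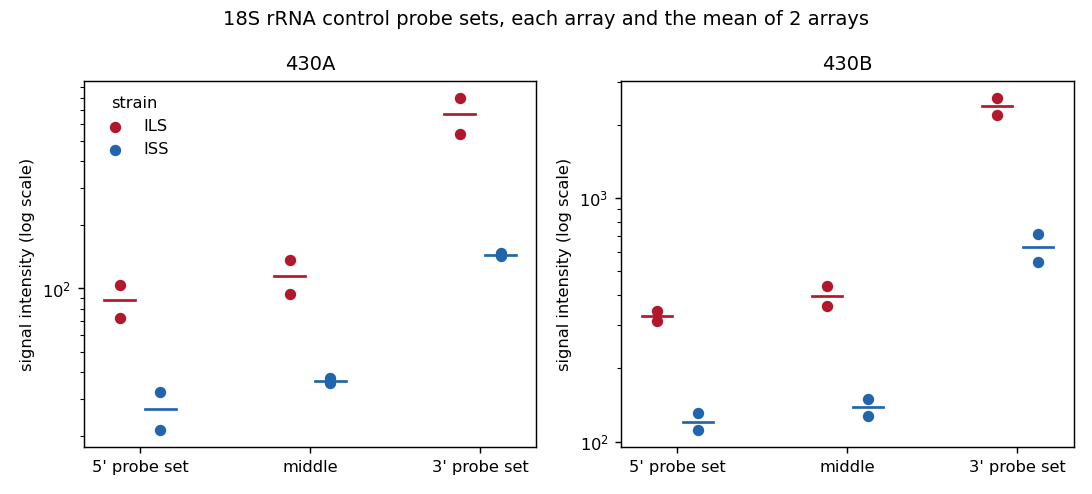
Signal intensity (y axis, log scale) of the 5', middle and 3' control probe sets for 18S ribosomal RNA on 430A (left) and 430B (right), with a point per array and a line at the mean of the 2 arrays of a strain. On both arrays each ILS value of the 3' probe set lies above each ISS value, with means 4.63-fold higher in ILS on 430A and 3.8-fold higher on 430B.

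On 430A, among genes higher in ILS, Psmd6, a proteasome subunit, had a mean signal of 1018 ± 225 in ILS against 87.88 ± 32.7 in ISS (SD, n = 2), at least 4.83-fold higher because both ISS values lay below the median of their arrays. Syt4, a synaptotagmin of secretory vesicles, was 4.61-fold higher in ILS. Vamp3, a SNARE protein of vesicle fusion, was 4.1-fold higher at its called probe set. Its other probe sets had log2 fold changes of 0.37, -0.09 and 0.11 and were not called. Cplx2, a complexin that acts at the synaptic vesicle, stood at 3486 ± 371 in ILS and 1166 ± 70.7 in ISS, a log2 fold change of 1.58 ± 0.13 (SE), while its probe sets on 430B stood at -0.24 and -0.13 and were not called. The orphan receptor Gprc5b (log2 fold change 1.81), the lysosomal trafficking protein Vps41 (1.80) and the nuclear pore protein Pom121 (1.79) were also higher in ILS. So were the cell surface proteoglycan Sdc4 (1.71) and the mitochondrial import protein Chchd4 (1.64). Ggps1, an enzyme of isoprenoid synthesis, was at least 2.6-fold higher.

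Among genes higher in ISS on 430A, Gnb1, a G protein beta subunit, had a mean of 5203 ± 250 in ISS against 774.4 ± 53.9 in ILS (SD, n = 2), a log2 fold change of -2.75 ± 0.12 (SE, limma adjusted p = 5.16e-05). The MHC class I heavy chain H2-D1 stood at 3181 ± 410 in ISS and 286.9 ± 39.4 in ILS (-3.47). H2-K1, a second class I heavy chain, was at least 5.45-fold higher in ISS, the actin-binding protein Cap1 at least 7.36-fold and the ribosomal protein gene Rps9 at least 4.45-fold. Anp32a, a nuclear phosphoprotein, had a log2 fold change of -2.93, while its other, brighter probe sets stood at -0.22 and -0.24 and were not called. Kcnip3, a calcium-binding partner of potassium channels, was at least 2.01-fold higher in ISS, while its other probe set stood at 0.74 (adjusted p = 0.0616). Adi1, of methionine salvage, was at least 3.45-fold higher in ISS, the microtubule-associated Clip4 at least 2.8-fold and Pigo, of GPI anchor synthesis, at least 3.02-fold. Clip4 and Pigo each had a further probe set called in the same direction. Another of Clip4 stood at 0.11 and another of Pigo at 0.22, neither of them called. The probe sets of Vamp3, H2-K1, H2-D1 and Rps9 are of the kind marked x, some of whose probes match other sequences.

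In all, 332 of the 11313 tested probe sets on 430A passed limma at an adjusted p under 0.05. Of these, 182 were higher in ILS and 150 higher in ISS, and 119 differed at least 2-fold. No single gene symbol was given for 45 of them, and the rest stood for 264 genes. The values of the strains did not overlap in 54.3% of tested probe sets, against 33.3% by chance. The count depended on single mice, at 115 without ILS replicate 48, 167 without ISS replicate 56 and 626 without ISS replicate 55, and on scaling, since equal array medians gave 1174 calls with 19.1% higher in ILS, against 54.8%. It fell to 136 with no filter on dim probe sets, 163 with a stricter one and 208 with both chips adjusted together. Strain could not be told apart from fluidics station, since both ILS arrays ran on station 2 and both ISS arrays on station 1. Nor could strain be told apart from scan order, since both ILS arrays were scanned before both ISS arrays.

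**Figure D2:**
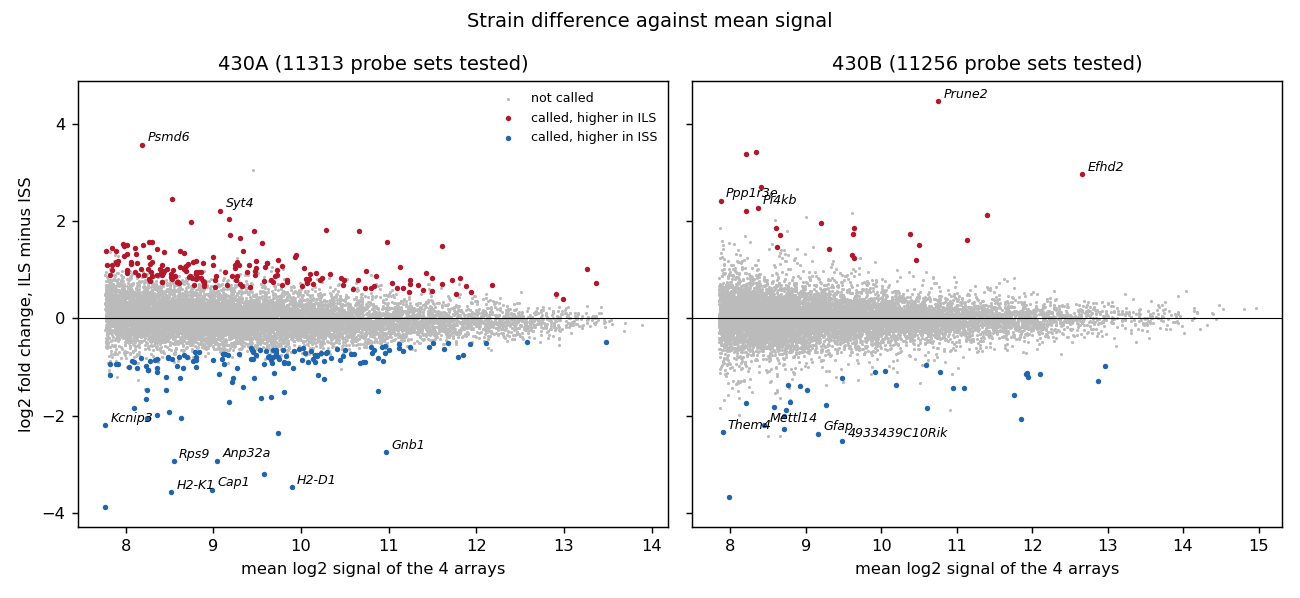
Log2 fold change (ILS minus ISS, y axis) against the mean log2 signal of the 4 arrays (x axis) for every tested probe set of 430A and 430B, with called probe sets in red (higher in ILS) or blue (higher in ISS) and the named genes of largest change labelled. On 430A 332 of 11313 probe sets were called and on 430B 54 of 11256, and the measured folds are drawn also where the text gives a lower bound.

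Each list member was counted at its brightest probe set. Of the gene lists, markers of Purkinje cells were lower and markers of microglia higher in ILS on 430A (camera adjusted p = 0.000214 and 0.000101 over 31 lists tested). Neither call held with an estimated correlation (camera adjusted p = 0.81 for each list). The estimate was 0.596 for the Purkinje list and 0.18 for the microglia list, against the preset 0.01. That form of the test rests on 2 residual degrees of freedom, so its failure alone does not decide against a list. The Purkinje list had 21 measured genes with a median log2 fold change of -0.415. Icmt (-0.87 ± 0.12, SE) and Ppp1r17 (-0.90 ± 0.14), a phosphatase inhibitor of Purkinje cells, fell past the threshold, and 19 members did not pass. Adjusted over the list alone, 11 members passed, all lower in ILS, among them the Purkinje markers Pcp2 (-0.49) and Slc1a6 (-0.46). The microglia list had 12 measured genes with a median of 0.443. The complement components C1qb (1.05 ± 0.15, SE) and C1qc (1.00 ± 0.19), the lysosomal protein Laptm5 (0.88) and the protease Ctss (0.84) rose in ILS, 8 members did not pass, and 5 passed when adjusted over the list alone. The receptor genes Cx3cr1 (0.49) and Csf1r (0.13), among the markers set beforehand, were not past the threshold. On 430B the probe sets of Laptm5 were not called. The calls of Laptm5 and Ctss ended without ILS replicate 48, ILS replicate 51 or ISS replicate 56, that of C1qc without ILS replicate 51 or ISS replicate 56, that of C1qb without ILS replicate 48 and that of Ppp1r17 without ISS replicate 56. Without ISS replicate 56 the adjusted p of the Purkinje list was 0.0817. The 18S control signal given above moved with strain as these lists did.

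**Figure D3:**
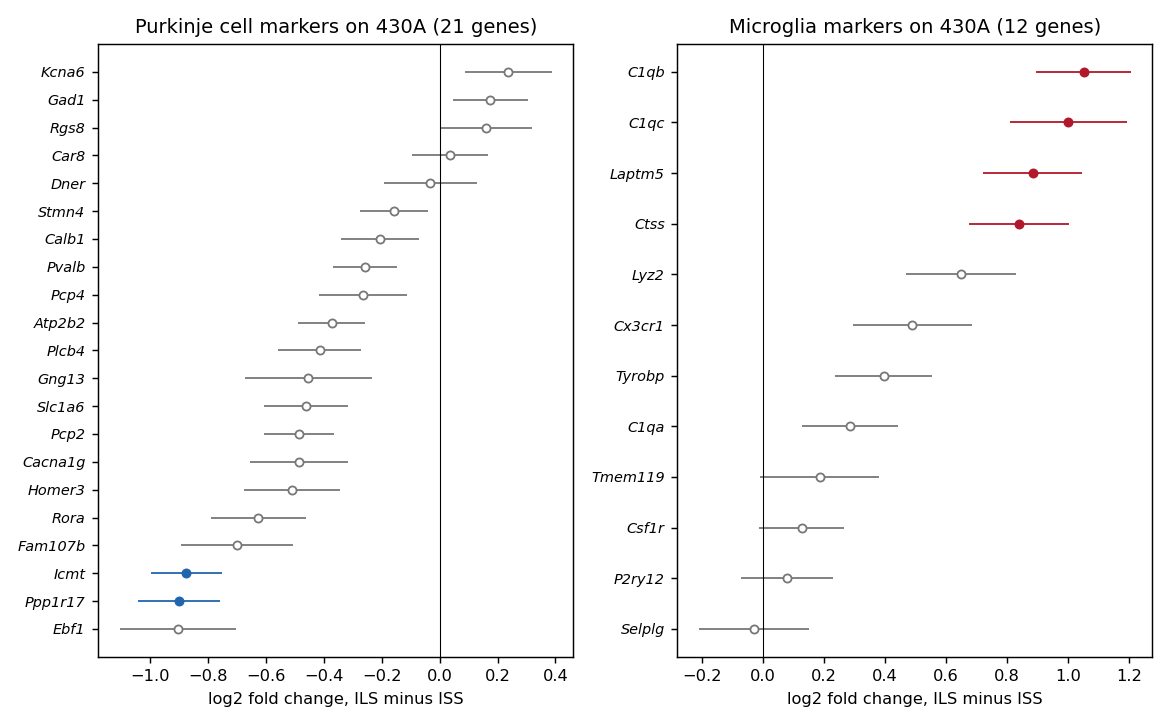
Log2 fold change (ILS minus ISS, x axis) of each measured marker gene of Purkinje cells (left, 21 genes) and microglia (right, 12 genes) on 430A, with bars for the standard error and filled points for genes past the adjusted threshold. The medians were -0.415 and 0.443, and 4 microglia markers and 2 Purkinje markers passed.

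The other cell type lists did not pass camera on 430A. Of 23 oligodendrocyte markers, Cldn11, a tight junction protein of myelin, rose in ILS (0.78) and 22 did not pass, with 1 past the threshold over the list alone. Of 9 choroid plexus and meninges markers, the matrix protein Dcn was called higher (0.65, adjusted p = 0.0498) and 8 did not pass, with 2 over the list alone. The Dcn call ended in 7 other settings, among them by definition the 2-fold minimum, and with any 1 of the 4 mice left out. The Cldn11 call ended without ILS replicate 48 or ISS replicate 56. A dimmer probe set of the oligodendrocyte marker Gsn was called in the opposite direction to Cldn11, at -1.22, while the brightest stood at -0.41. No member passed over all genes among 29 markers of Bergmann glia and astrocytes (median -0.0884), 18 of granule cells (-0.102), 12 of interneurons and unipolar brush cells (-0.147), 19 of endothelium and pericytes (-0.0618) and 11 of brainstem, midbrain and forebrain neurons (0.232). Adjusted over the list alone, 5 of the Bergmann glia and astrocyte markers passed, among them Gfap (-1.05) and Glul (0.43), and 3 of the granule cell markers. Under other settings the granule cell list passed camera as lower in ILS with no filter, without ILS replicate 48 and without ISS replicate 55, the Bergmann glia and astrocyte list as lower with no filter, and the brainstem list as higher without ISS replicate 55. The 3 measured blood markers were too few for the test (median -0.207).

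Several lists of neuronal signalling held called members on 430A, with none of these lists past camera in the setting used. The neuropeptide list passed as higher in ILS with equal medians, with no filter, without ISS replicate 55 and with either other choice of probe set per gene, the calcium list as lower with no filter and with the stricter filter, and the ionotropic glutamate list as lower without ILS replicate 48. Of 34 synaptic vesicle genes, Cplx2, Syt4 (0.87 for the brighter of its probe sets) and Amph (0.59) rose in ILS, Pclo (-0.69), a scaffold of the active zone, fell, and 30 did not pass, with 5 over the list alone. Dimmer probe sets of Vamp3 (2.03) and Syt11 (0.70), members counted as not passing, were called, as was one of Kcnip3 (at least 2.01-fold higher in ISS) among the potassium channels. Of 17 neuropeptide genes, Oxt (1.10), which encodes oxytocin, and the nociceptin receptor Oprl1 (0.71) rose and 15 did not pass, with 3 over the list alone. The pacemaker channel Hcn2 (1.04) rose among 6 sodium and HCN channels, the inward rectifier Kcnj9 (-0.87) fell among 24 potassium channels, and Cacng2 (-0.71), which regulates calcium channels and AMPA receptors, fell among 17 calcium channel and release genes. Adjusted over the list alone, these lists had 1, 3 and 2 members past the threshold. Other probe sets of Pclo stood at 0.01 on 430A and 0.40 on 430B (adjusted p = 0.453), that of Kcnj9 on 430B at 2.09 ± 0.77 (SE, adjusted p = 0.426) and those of Cacng2 on 430B at 0.55 and -0.02, none of them called. The Amph call ended with any 1 of the 4 mice left out, those of Oprl1, Kcnj9 and Cacng2 without ILS replicate 48, ILS replicate 51 or ISS replicate 56, that of Hcn2 without ILS replicate 48 or ISS replicate 56, that of Pclo without ILS replicate 51 or ISS replicate 56 and in 6 other settings, and that of Oxt without ILS replicate 48. For Pclo the other settings include, by definition, the 2-fold minimum. The 6 ionotropic glutamate receptors had no called member, a median of -0.388 and a camera adjusted p of 0.0787, and 4 members passed over the list alone, among them Grin2c (-0.58) and Gria2 (-0.45). Of 6 GABA-A receptor subunits none passed, with Gabrd at -0.47 (adjusted p = 0.12) and Gabrg1 at 0.52 (adjusted p = 0.143), and none over the list alone.

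In the lists of metabolism, stress and immunity on 430A, H2-D1 and H2-K1 fell in ILS among 9 MHC genes and 7 did not pass, with 3 over the list alone. The interferon-induced Ifitm3 (1.15) rose among 7 interferon-stimulated genes, the cochaperone Fkbp4 (-0.91) fell among 39 heat shock and chaperone genes, the complex I subunit Ndufs5 (0.80) rose among 71 oxidative phosphorylation genes, and Rpl37 (0.75) rose among 40 ribosomal protein genes. Over the list alone, 2, 1, 1 and 2 members passed in these lists. The Rpl37 call ended without ILS replicate 48, ILS replicate 51 or ISS replicate 56 and the Fkbp4 call without ILS replicate 48 or ISS replicate 56. Dimmer probe sets of Rps9 (at least 4.45-fold higher in ISS), Ndufc2 (0.93) and the chaperone Hspa5 (-0.71), members counted as not passing, were called. Camera passed none of these lists in the setting used. The oxidative phosphorylation list, with a median of -0.0979, passed as lower in ILS with equal medians and with no filter, the heat shock and chaperone list as lower with no filter, and the monoamine list as higher with no filter and without ILS replicate 48 or ISS replicate 55. At the brightest probe set no member passed over all genes among 14 genes of alcohol and aldehyde metabolism (median 0.0606), 7 of GABA synthesis and transport (0.0763), 8 metabotropic glutamate receptors and transporters (-0.0416), 6 monoamine genes (0.289), 23 of cyclic AMP signalling (-0.0189), 18 of protein kinase C signalling (0.0178), 15 immediate early genes (-0.00917), 36 antioxidant genes (0.0228), 20 of cholesterol synthesis (0.0954) and 14 clock genes (0.0163). A dimmer probe set of Hmgcs1, of cholesterol synthesis, was called at 0.74, while the brightest stood at -0.31. Over the list alone, 3 clock genes, among them Per3 (-0.71), and 3 metabotropic glutamate receptors and transporters passed, and none in the rest of these. The 4 measured glycine, nicotinic and 5-HT3 receptors were too few for the test (median 0.361). Median and mean differed in sign for the MHC (0.058 and -0.665, the mean with H2-K1 at its measured value), synaptic vesicle, sodium channel, protein kinase C, endothelium and clock lists, and the median and the test for the cyclic AMP list.

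On 430B, Prune2 gave the largest difference named, at 8428 ± 3330 in ILS against 369.2 ± 49.1 in ISS (SD, n = 2), a log2 fold change of 4.46 ± 0.25 (SE). Another probe set of Prune2 was called the opposite way, at -2.06. The calcium-binding protein Efhd2 was 7.8-fold higher in ILS, while its probe set on 430A had a log2 fold change of 0.03. Ppp1r3e, a glycogen-targeting phosphatase subunit, was at least 2.28-fold higher in ILS and the lipid kinase Pi4kb at least 3.04-fold. Another probe set of Pi4kb had a log2 fold change of -0.51 and was not called. Higher in ISS were Gfap, the intermediate filament protein of astrocytes, at 1320 ± 354 against 253.2 ± 48.1 (log2 fold change -2.37), the transcript 4933439C10Rik (-2.52), the thioesterase Them4 (at least 2.18-fold) and Mettl14, of the RNA adenosine methyltransferase (at least 3.05-fold). The Ppp1r3e call ended without ILS replicate 48, ILS replicate 51 or ISS replicate 56, that of Pi4kb without either ILS replicate, that of Mettl14 without ILS replicate 48 or ISS replicate 56, and that of Them4 without ILS replicate 51 or either ISS replicate.

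In all, 54 of 11256 tested probe sets on 430B passed limma, with 22 higher in ILS and 32 higher in ISS, and 52 of them differed at least 2-fold. No single gene symbol was given for 13 of them, and the rest stood for 39 genes. The strains did not overlap in 38.9% of tested probe sets, against 33.3% by chance. The count was 30 without ILS replicate 48, 25 without ILS replicate 51, 34 without ISS replicate 56, 94 with both chips adjusted together, 13 with no filter on dim probe sets and 4 without the intensity trend in the variance. ILS replicate 48 alone ran on station 1, so a station block fitted that array exactly and left ILS replicate 51 against both ISS arrays. This gives the same fold changes as leaving out ILS replicate 48 and cannot tell the station from that mouse. With the block the calls of Ppp1r3e, Pi4kb, Gfap, Them4, Mettl14, Camk4, Slc17a7 and Car8 ended. Scan order separated the strains on 430B as well, with both ISS arrays scanned before both ILS arrays.

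GABA-A receptor subunits were higher in ILS as a list on 430B, the only list of 23 tested there that passed camera (adjusted p = 0.00207). With an estimated correlation the list did not pass (camera p = 0.0558, adjusted p = 0.913). The estimate, -0.122, lay below the preset 0.01, so a higher correlation did not cause that loss. That form of the test rests on 2 residual degrees of freedom. All 8 measured subunits had positive values, with a median of 0.396, but none passed over all probe sets, and Gabra5 (0.80 ± 0.21, SE) alone passed over the list alone. Gabra2 was at 0.57. On 430A the 6 measured subunits had a median of 0.0592, with 3 positive, and the list did not pass (camera adjusted p = 0.775). Gabrd, chosen after its values were seen, was at 0.41 on 430B against -0.47 on 430A, and the difference between the arrays was not tested. The 18S control signal was higher in ILS on this array too. Elsewhere Slc17a7 (-1.14), the vesicular glutamate transporter of granule cells, fell in ILS among 10 granule cell markers and 10 metabotropic glutamate receptors and transporters. Gfap fell among 6 Bergmann glia and astrocyte markers, and the kinase Camk4 (-0.98) among 12 measured genes of the brainstem, midbrain and forebrain list. Camk4 was bright in these cerebellar samples (5739 in ILS and 11310 in ISS), so its listing does not tell which cells it came from. Car8 (1.51), a Purkinje cell protein, rose among 7 Purkinje markers, a list that did not pass on 430B (median -0.178, mean 0.0267, camera adjusted p = 0.826). The probe sets of Camk4 on 430A stood at 0.46 and 0.11 and were not called. The calls of Slc17a7 and Camk4 ended without ILS replicate 48, ILS replicate 51 or ISS replicate 56, and that of Car8 without ILS replicate 48. All 3 also ended with the station block, which is no separate check, since it leaves ILS replicate 51 alone against both ISS arrays. Without ILS replicate 48 the metabotropic glutamate, granule cell and Bergmann glia lists also passed camera, as lower in ILS. Adjusted over the list alone, 1 member passed in each of these lists.

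The other lists on 430B had no member past the threshold over all probe sets. These were 9 glycine, nicotinic and 5-HT3 receptors (median 0.417, camera adjusted p = 0.0927), 10 ionotropic glutamate receptors (-0.0443), 10 monoamine genes (0.0955), 8 neuropeptide genes (0.0709), 19 potassium channels (-0.0572), 15 calcium channel genes (-0.0215), 8 sodium channels (0.181), 23 cyclic AMP genes (0.0279), 11 protein kinase C genes (-0.14), 19 synaptic vesicle genes (0.0578), 15 chaperones (-0.0362), 6 antioxidant genes (-0.00943), 8 oxidative phosphorylation genes (0.0158), 5 interferon-stimulated genes (0.354), 5 genes of cholesterol synthesis (0.00899), 7 clock genes (0.23) and 6 interneuron markers (-0.312). Over the list alone, 2 clock genes (Per3 at 0.78 and Rorb at 0.63) and Stard4 of cholesterol synthesis (-0.51) passed. Per3 had the opposite sign on 430A, where it also passed over the list alone, at -0.71. Median and mean differed in sign for the potassium channel, calcium channel, chaperone, antioxidant, oxidative phosphorylation, cholesterol, Purkinje and brainstem lists. Lists with fewer than 5 measured genes were not tested, among them 2 microglia markers (median -0.0713), 4 oligodendrocyte markers (0.107), 3 endothelial markers (-0.226), 4 choroid plexus markers (0.0976), 4 genes of alcohol metabolism (0.0328), 3 of GABA synthesis (-0.125), 3 immediate early genes (0.018) and 2 ribosomal protein genes (-0.449). Of these, Opalin of the oligodendrocyte list (0.50) and Rps3 of the ribosomal list (-1.003) passed over the list alone. No gene of the MHC and blood lists had a probe set with 1 symbol among those tested on 430B.

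Some differences reached every probe set of a gene on 430A and others only 1 of them. Both probe sets of Gnb1 (-2.75 and -2.35), H2-D1 (-3.47 and -3.20), Syt4 (2.20 and 0.87) and Sdc4 (1.71 and 0.93) were called in the same direction. The second probe set of Psmd6 stood at -0.28 (adjusted p = 0.277), that of Rps9 at 0.03, that of H2-K1 at 0.47 and that of Gprc5b at -0.07, none of them called. That of Pom121 stood at 0.27 and was not called either. Vps41 and Ggps1 each had a further probe set called in the same direction. Another of Vps41 stood at -0.03 and others of Ggps1 at 0.13 and -0.14, none of them called. Of 21 genes with 2 or more called probe sets, 6 were higher in ILS and 11 higher in ISS at each called probe set, and 4 had calls in both directions. These 4, named because of that result, were Adi1 (at least 3.45-fold higher in ISS, -1.03 and 1.09), Smim10l1 (at least 2.64-fold higher in ISS and 1.55), Ptp4a2 (-1.03 and 0.71) and Slc25a51 (-0.76 and 0.69).

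Over the 154 genes on 430A with a called probe set and at least 1 other, 171 of 278 other probe sets had the sign of the called one, a share of 61.5% (exact 95% interval 55.5% to 67.3%, two-sided exact binomial p = 0.000148). Among genes without a call the share was 54.1%. With 1 other probe set per gene the share was 60.4%, against 54.2% for genes without a call (exact binomial p = 0.125), and under the alternatives 67.7% against 56.7% with no filter (p = 0.08), 66.1% against 53.2% with the stricter filter (p = 0.0607) and 64.7% against 53.3% with quantile normalization (p = 0.013). Of the other probe sets, 70 passed an unadjusted p of 0.05 in the same direction and 20 in the opposite one, a same-direction share of 77.8% against 68.2% among genes without a call. With 1 per gene the share was 78.9% (exact binomial p = 0.056 against genes without a call). The median log2 fold change in the direction of the call was 0.103, against 0.871 for the called probe sets. On 430B 20 of 31 other probe sets shared the sign (64.5%, exact binomial p = 0.15), against 56.7% for genes without a call (exact binomial p = 0.47). With the stricter filter the share was 76.9% (exact binomial p = 0.00936), and with that filter and 1 other probe set per gene it was 66.7% (exact binomial p = 0.238). The probe sets of one gene were measured in the same mice.

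**Figure D4:**
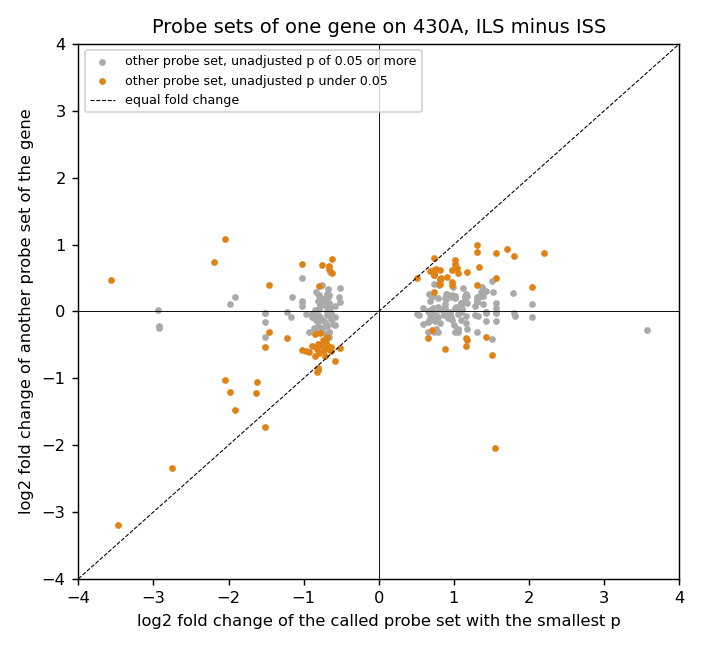
Log2 fold change (ILS minus ISS) of the called probe set with the smallest p (x axis) against that of each other tested probe set of the same gene (y axis) on 430A, 278 pairs from 154 genes. Points on the dashed line changed equally, and 61.5% of the points have the same sign on both axes.

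The 2 arrays gave strain differences that were weakly related across genes. Pink1, a mitochondrial kinase, was called higher in ILS on both (0.62 on 430A and 2.12 on 430B), and Them4 (-0.72 on 430A and at least 2.18-fold on 430B) and Mrpl35 (-0.83 and -1.08), of the mitochondrial ribosome, were called lower on both. These were the 3 genes called on both arrays, named for that reason. The 99 probe sets tested on both arrays, none of them called, had log2 fold changes that correlated at r = 0.338 (permutation p = 0.00066) and Spearman's rho = 0.247 (permutation p = 0.0138). For 1630 genes with different probe sets on each array, r was 0.114 (permutation p = 1e-05, the smallest that 100000 permutations can give) and rho 0.102 (permutation p = 7e-05), and r was 0.059 with no filter and 0.152 with the stricter filter. For the probe sets on both arrays r ran from 0.288 with quantile normalization to 0.426 with the stricter filter. With quantile normalization their rho was 0.193 (permutation p = 0.0554). Of 50 of these genes called on 430A, 30 had the same sign on 430B (60%, two-sided exact binomial p = 0.203). These correlations are across genes, which are not independent replicates, and both arrays held RNA of the same 4 mice.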

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

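The tests of explanations here were chosen only after the results were seen, while those with an estimated correlation were planned.

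The control probe sets for 18S ribosomal RNA, which no comparison uses, were higher in both ILS arrays than in both ISS arrays of each chip. The 3' probe set was 4.63-fold higher on 430A and 3.8-fold higher on 430B (2 arrays against 2, where the smallest two-sided exact permutation p is 0.333), and the bioB spike-in control was 1.18-fold and 1.28-fold higher. The fluidics station is argued against on 430B, where ILS replicate 51 ran on the station of both ISS arrays and stood 4.11-fold above their mean. For more degraded RNA in ILS, 0 of 4 ratios of 3' to 5' signal (actin and Gapdh on each chip) were higher in both ILS arrays than in both ISS arrays, which gives it no backing, but it is not excluded, since the strains overlapped in each ratio (ILS over ISS 0.972 to 1.02). A strain difference, and carry-over of ribosomal RNA into labelling, were not tested.

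The 3 splits of the 4 arrays are too few for a share under 0.05: with limma the real split, 1 of the 3, gave 332 calls on 430A and the highest other 0 (2467 against 101 and 121 at an unadjusted p under 0.05), and on 430B 54 and 0 (1015 against 184 and 642). A strain variant under the probes stays open as a cause of the calls, since with 1 other probe set per gene the same-sign share was 60.4% against 54.2% for genes without a call (exact binomial p = 0.125, and 0.013 to 0.08 over 3 alternatives, under 0.05 with quantile normalization alone), a comparison preferred, after both were seen, to that of all other probe sets (61.5% against 54.1%, p = 0.0135), since probe sets of one gene are not independent. The 4 genes called in both directions (Adi1, Smim10l1, Ptp4a2 and Slc25a51) may carry such a variant or differ in transcript forms. The fluidics station, which cannot be told apart from strain on 430A, stays open. Within station 2 on 430B, with 1 ILS array against 2 ISS arrays, 58.7% of 63 called genes had the same sign. These were taken at the called 430A probe set of smallest p. All 4 arrays gave 60% of 50 genes whose brightest 430A probe set was called. The shares are close and rest on different genes as well as arrays, so this comparison decides nothing. A difference in transcript level between the strains stays open too, as untested. The scan order, which separated the strains on both chips, was not tested either.

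The Purkinje list was lower and the microglia list higher in ILS on 430A, where the median fold change fell from 0.101 in the dimmest probe sets to -0.0697 in the brightest. That trend with signal is argued against as the whole cause, since cyclic loess normalization, which removes it, left medians of -0.39 (Purkinje, adjusted p = 0.00125) and 0.338 (microglia, adjusted p = 0.000399). The microglia median exceeded that of the Bergmann glia, oligodendrocyte and endothelium markers, at -0.0528, by 0.496 (permutation p = 8e-05, across genes). This cannot decide against a lower share of neurons that raises all other types alike. The list was picked after it passed in these same data, and the permutation treats genes as independent. The estimated correlation was 0.18 between the microglia genes and 0.596 between the Purkinje genes, against the preset 0.01 of the camera test used. The fluidics station and the scan order cannot be told apart from strain here. On 430B the Purkinje list did not pass (7 markers, median -0.178, mean 0.0267, camera adjusted p = 0.826). Of its members 3 were positive, among them its 1 called member, Car8 (1.51), and 2 microglia markers were too few to test. More microglia or higher activity per cell, and a strain difference in Purkinje cells, stay open as hypotheses. Neither list passed with an estimated correlation (camera adjusted p = 0.81), a form of the test limited by 2 residual degrees of freedom.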

How the results depend on the processing

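No paired analysis was possible because the 2 strains share no replicate numbers. On 430A, 332 probe sets were called, against 1174 with equal array medians (19.1% higher in ILS against 54.8%), 136 with no filter, 163 with the 75th percentile filter, 208 with both chips adjusted together and 119 with a 2-fold minimum, and 115 (without ILS replicate 48) to 626 (without ISS replicate 55) with 1 mouse left out. Equal medians moved the median fold change by -0.158, in dim and bright probe sets alike. It went from 0.101 to -0.058 in the dimmest probe sets and from -0.0697 to -0.228 in the brightest. Of the 332 calls, 313 were among the 1174. On 430B, 54 were called, against 13 with no filter, 4 without the trend, 94 with joint adjustment and 24 with the station as a block, and 25 (without ILS replicate 51) to 67 (without ISS replicate 55) with 1 mouse left out. Of 2 lists called on 430A, 0 were with an estimated correlation and 0 with fry, against 4 with equal medians, 9 with no filter and 1 (without ISS replicate 56) to 6 (without ISS replicate 55) with 1 mouse left out. Of 1 list on 430B, 0 were with an estimated correlation and 0 with fry, and 1 to 4 (without ILS replicate 48) with 1 mouse left out. The form with an estimated correlation rests on 2 residual degrees of freedom, so its failure alone does not decide against a list. The same-sign share of other probe sets on 430B was 76.9% with the 75th percentile filter (64.5% with the filter used, and 66.7% with the stricter filter and 1 other probe set per gene). A different set tested changes the adjustment. With a mouse left out the same probe sets were tested, while the fold changes, standard errors and residual degrees of freedom changed. Beyond these and the shift of all fold changes with equal medians, the cause of the shifts was not tested.

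Adjusted p-values over the alternatives ran from 2.58e-08 to 0.81 for the Purkinje list, 4.85e-06 to 0.81 for the microglia list and 0.00201 to 0.913 for the GABA-A list. Of 51 named results, 24 stayed past the threshold in each setting that keeps all mice and tested them, and 0 changed direction. These settings include the 2-fold minimum, which reuses the same fit, so 16 results with smaller changes were lost there by definition. Not all of the 24 also stayed with each mouse left out. Leaving out a mouse could not change the direction where the values of the strains did not overlap. The 75th percentile filter tested 25 of the 51, quantile normalization 50 and the station block the 11 of 430B. That block amounts to leaving out ILS replicate 48 there. With no filter 22 of these were no longer past the threshold, and without the trend 17. The microglia list had too few genes under the 75th percentile filter to be tested. Signal over background limits dim probe sets, for which no detection calls were used. The added cyclic loess normalization was chosen after seeing the data and gave 276 calls on 430A and 63 on 430B.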

Other observations

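The test of neighbouring genes was chosen only after the result was seen. Several called genes lay beside another called gene in the order of assembly GRCm38.p6, among them Cap1 beside Ppt1 (both lower in ILS), Vps41 beside Amph (both higher), C1qb beside C1qc (both higher) and Pclo (lower) beside Sema3e (higher), pairs chosen after their values were seen. The hypothesis was that strain segments hold several differing genes. Of 11122 genes placed, 299 were called on either array, and 13 neighbouring pairs were both called, against a mean of 8 over 100000 permutations (permutation p = 0.0581). With overlapping genes and genes sharing their first 3 letters left out, such as C1qb and C1qc, there were 11 pairs against a mean of 7.2 (permutation p = 0.107), and 5 of the 11 changed in the same direction. The hypothesis stays open.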
